A study of Homo sapiens with 2 samples.

How the data were processed

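RNA from MDA-MB-231 cells, an established human breast cancer line, was measured on 2 oligonucleotide microarrays with 2 colours each. Per the labels, cells were collected 72 h after lipofection of double-stranded oligonucleotides. RNA of decoy-transfected cells carried Cy3 (green) and RNA of scrambled-transfected cells carried Cy5 (red) on both arrays. Each array holds its own decoy and its own scrambled oligonucleotide, and the design text treats the pair of sets as biological replicates. The dyes were not swapped, so a dye effect and the effect of the decoy cannot be told apart. Both arrays lie on the same slide, so slide is no batch between them.

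Per the file headers and the submitters' processing notes, the slides were read with Agilent Feature Extraction 9.5. The deposited scanner files hold, for each of 45015 features, spot and local background intensity in each channel on a linear scale, a log10 ratio of red over green, a p-value of that ratio from the software's error model, and other pixel statistics such as the number of pixels per spot. The value table of the series holds log10 ratios, and 100% of its entries equal minus the scanner log ratio within 1% on both arrays, so its scale and direction (green over red) are known. Its medians were 0 on array 1 and 0.0598 on array 2, and no centring beyond the software's dye normalization is recorded in the sources used here.

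The first check concerned which probe each spot carries. Probes printed more than once should give like signals at all of their spots. As deposited, the variance of log2 green signal within such probes was 0.916 of the total on array 1 and 0.892 on array 2, so spots of the same probe differed about as much as spots of different probes. The layout was therefore moved against the measured grid by 861 combinations of row and column shifts. On array 1 the within-probe share fell to 0.0034 when the signal of a probe was read 1 column lower than its listed column, and the next best shift gave 0.857. On array 2 it fell to 0.0983 when the signal was read 2 rows lower than the listed row, and the next best gave 0.857. The red channel gave the same shifts. Negative control probes had a median green signal of 228.7 on array 1 as listed and 34 after the move, and of 99.7 on array 2 as listed and 38.2 after it. In each of 18 blocks of the grid, replicate spots correlated with their probe's median at 0.997 or more on array 1 and at 0.718 or more on array 2. The search found the right shift on 3 of 3 simulated grids. All gene-level values below use the moved layout. This choice was made after seeing the data, and the values with names as listed are among the alternatives.

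The second check concerned the green values. On both arrays the same 3637 non-control features (3331 probes, 8.38% of non-control features) carry green values written with more than 6 significant digits in columns that otherwise hold at most 6. No red value and no control feature does so. In these features 16.7% of green mean signals on array 1 and 9.95% on array 2 are whole pixel sums, against 100% in the other features. The listed p-value differs by more than 0.01 from the one implied by the log ratio and its error in 99.3% of them on array 1 and 95.9% on array 2, against 0% elsewhere. The software's own summary lists 20224 features with a negative subtracted green signal on array 1 and 9377 on array 2, while the files hold 19188 and 10896. The red counts match the summary exactly, with 20690 and 7034. Nothing in the sources used here records how these green values came about. They were left out of the main fits, also after seeing the data, and were kept in named alternatives.

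The analysis written before the data were examined was followed except for the layout, the left-out features, the background limit and the spot flags. These 4 departures were chosen after seeing the data. Mean signals were corrected with the normexp method (offset 50) against the median local background, normalized within each array by loess with control spots at weight 0, and turned to log2(decoy/scrambled). Spots of a probe were averaged. Because the software's well-above-background flag rests on misplaced negative controls, a probe counted as above background in a channel when its signal exceeded the median of the moved negative controls by 3 median absolute deviations, which put the limits at 44.3 (green) and 58.3 (red) on array 1 and at 52.0 and 76.3 on array 2. Probes above it in at least 1 channel on both arrays were kept, which left 26517 probes. Non-uniformity flags were not applied, since they mark 56.9% of green and 63.5% of red features on array 2. Saturated spots were kept, as planned. Because red was saturated on array 1 for 1400 tested probes and green for 386, and such ratios are not measured in full, a fit without the probes that had a saturated spot was added after seeing the data.

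The mean of the 2 ratios was tested against 0, two-sided, with limma 3.58.1 in R 4.3.3 (lmFit and eBayes) and Benjamini-Hochberg adjustment at 0.05. The 19 gene lists were fixed before the data were examined and tested with camera at a preset correlation of 0.01, adjusted over the lists, and also with an estimated correlation and with fry. With 2 arrays the estimated correlation and fry have a single residual degree of freedom, so they can hardly call any list. For each array alone, a list's median was placed among 10000 random lists of the same size matched on intensity, which describes these arrays and tests no condition. Gene symbols came from the array design's accessions through the RefSeq table of GRCh38.p14, or from the design's gene name where it is a current symbol or a single synonym. A current symbol was found for 26794 of 41000 probes, and the file's name was kept for the other 14206. Each gene was represented by its brightest probe, which gave 13205 genes. Probe coordinates are those of the scanner files, whose header names the build hg17.

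Genes were named by a rule written before the data were examined. It takes the 12 higher and 12 lower genes with the largest smaller-of-the-arrays ratio in the same direction on both arrays, filled from genes that missed the threshold where too few passed, up to 4 members per list by the same ranking, and ACTB, GAPDH, HPRT1 and TBP. The software's own calls (p under 0.01 on a single array) were counted as well. Alternatives covered background correction, normalization, the dim-probe filter, the variance model, separate channels, the value table, each array alone, the layout, the 3637 features, saturation and spot flags.

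The fit was tested on simulated data for the 26517 probes, each with a spread drawn at random from the SDs observed between the arrays. An SD of 2 values is noisy itself, so the simulated spread varies more between probes than the real one. Of 67 probes changed by 0.5, 67 changed by 1 and 66 changed by 2 on the log2 scale, 0 were recovered at each size. With a spread of 0.05 all were recovered, at 13 false calls. On reordered genes, the camera step found a list moved by 0.3 (adjusted p = 5.63e-15) and called 1 of the other lists. The planned comparison of promoters with and without the motif needs a genome sequence and was not analysed here.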

Results

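The study transfected MDA-MB-231 breast cancer cells with short double-stranded DNA carrying the motif AAAA[AGT]TT, a decoy that can compete with promoters for proteins binding this AT-rich element, and compared them with cells given scrambled oligonucleotides. Expression was measured 72 h later on 2 arrays with 2 colours, each with decoy RNA in green and scrambled RNA in red. Array 1 used the decoy caattGAAATTTTGagcaa, which holds 1 match to the motif on either strand, against gtTtATAcAcTaaaGaTGa, which holds 0. Array 2 used the decoy gctggAAAAAATTTaagac, with 2 matches, against aagATTgctAgAAgAaATc, with 0. There is 1 group of 2 ratios, and limma p-values of probes and genes measure the spread between these arrays, which differ in oligonucleotide as well as in culture. Camera p-values at the preset correlation compare a list with the other genes. They measure spread across genes and do not show that a shift was repeated on both arrays.

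The arrays differed in quality. On array 1 the median probe signal was 347 in green and 562 in red, against negative controls at 34 and 43.0. On array 2 it was 157.6 and 183.2, against 38.2 and 46.3, and the local background reached 126 and 159.5, compared with 38 and 43.5 on array 1. With normexp background correction, the ratio of a probe printed more than 4 times varied between its spots. Its pooled SD was 0.063 on array 1 and 0.23 on array 2 (233 probes, log2 scale). Without background correction the SDs were 0.086 on array 1 and 0.68 on array 2. With the software's processed signals they were 0.066 and 0.89. The spread between spots on array 2 thus depends strongly on the background correction, which limits what small array 2 ratios below can show. Listed spot names were displaced from the measured grid on both arrays, and all values below are for names moved back into register. The same 3637 features on both arrays held green values in another number format and were left out.

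**Figure D1:**
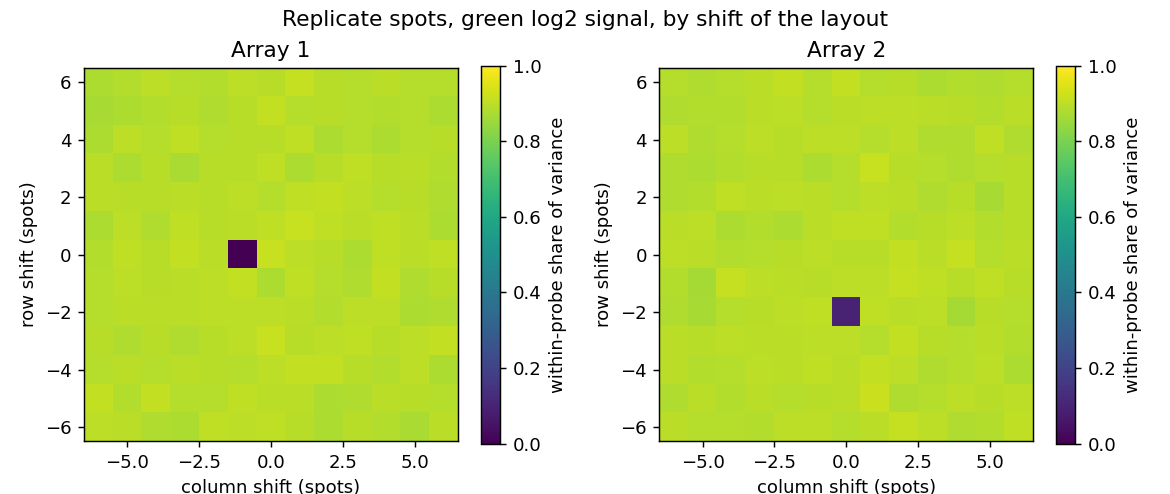
Share of the variance of log2 green signal that lies within probes printed more than once (colour, 0 to 1), for shifts of up to 6 spots of the printed layout against the measured grid in rows (y axis, spots) and columns (x axis, spots), per array. The share is lowest at a shift of -1 column on array 1 (0.0034) and at -2 rows on array 2 (0.0983), while no shift gives 0.916 and 0.892.

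The comparison of decoy with scrambled RNA asks which transcripts change when the motif is offered in excess. Genes without a saturated spot were ranked by the smaller of their ratios, so other genes stood further out on a single array or by mean. The highest by this ranking were LRWD1, a partner of the origin recognition complex, the spliceosomal Sm protein gene SNRPD3, the immunoproteasome subunit gene PSMB9 and the apoptosis inhibitor gene BIRC3. The lowest by it were FOLH1, which encodes a folate hydrolase, FKBP1A, which encodes the FK506-binding immunophilin, HIP1R, which encodes an endocytic adaptor, and the AP-1 subunit gene JUND. None of these passed the test, and 0 of 26517 probes were higher and 0 lower at an adjusted p of 0.05 with limma. At an unadjusted p under 0.05 there were 952 higher and 804 lower probes. This balance depends on the scaling, with 787 and 256 under median centring, 676 and 281 under scale normalization, and 701 and 3 in the uncentred value table. A fit of the separate channels gave 0 after adjustment as well. Limma on the software's processed signals gave 188 higher and 87 lower after adjustment, of which 44 had the same direction and an unadjusted p under 0.05 in the planned fit. In simulated data with spreads drawn from the SDs of these arrays, changes of 2 on the log2 scale were not recovered either (0 of 66). Those spreads vary more between probes than the real ones, so the simulation does not measure the power of this fit. With 2 arrays a count of 0 does not show that expression was alike.

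In the fit without saturated probes, LRWD1 stood at 0.61 on array 1 and 0.53 on array 2, a mean of 0.57 ± 0.055 (SD, n = 2) on the log2 scale. SNRPD3 had a mean of 0.52 ± 0.040 and PSMB9 had 0.56 ± 0.10. PSMD13, a proteasome regulatory subunit gene, had 0.46 ± 0.087. CFL1, which encodes the actin-severing protein cofilin, had 0.49 ± 0.072. NGDN stood at 0.53, OARD1 at 0.45, RRP1 at 0.42, TMEM39B at 0.40 and CLASRP at 0.38 as means over both arrays. Over all probes of the gene in the planned fit RRP1 stood at 0.26 and CLASRP at 0.06. The size of several depends on the background correction, since without it OARD1 stood at 1.10, CFL1 at 0.99 and TMEM39B at 0.73. The adjusted p of these higher genes was 0.879 in limma. These names were chosen after their values were seen, by the planned ranking applied to unsaturated probes. Ranking by the smaller ratio favours genes whose ratios happen to be alike on both arrays. The SDs of genes named this way, here and below, are therefore small in part through the choice and do not show close replication.

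On the lower side FOLH1 stood at -0.83 on array 1 and -1.23 on array 2, a mean of -1.03 ± 0.28 (SD, n = 2) in the same fit. Its probe is dim and its size depends on the background correction, at -2.77 without correction and -1.55 with processed signals. It lies at chromosome 11, positions 49124936 to 49124995 in hg17. FKBP1A had -0.83 ± 0.55 and HIP1R -0.52 ± 0.099. JUND had a mean of -0.44 ± 0.012, at chromosome 19, positions 18251756 to 18251814. SEC23A, a component of the COPII vesicle coat, had -0.46 ± 0.051, and TMEM167A had -0.46 ± 0.044. TTC3 stood at -0.44, the RNA helicase gene DDX3X at -0.43, the Golgi calcium pump gene ATP2C1 at -0.41, ZMYND11 at -0.41 and ZBTB38 at -0.41. VEGFA, the angiogenic growth factor gene, stood at -0.50. Several of these values rest on the brightest probe, since the median over all probes of the gene in the planned fit was 0.01 for FKBP1A, 0.02 for ATP2C1, 0.02 for VEGFA, -0.02 for DDX3X, -0.17 for TTC3, -0.20 for ZMYND11, -0.29 for TMEM167A, -0.35 for HIP1R and -0.37 for SEC23A. In that planned fit the brightest probe stood at -0.96 for FKBP1A, -0.54 for ATP2C1, -0.61 for VEGFA, -0.61 for DDX3X and -0.53 for TTC3. It stood at -0.59 for TMEM167A, -0.73 for HIP1R and -0.60 for SEC23A. The adjusted p was 0.879 for the lower genes too.

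**Figure D2:**
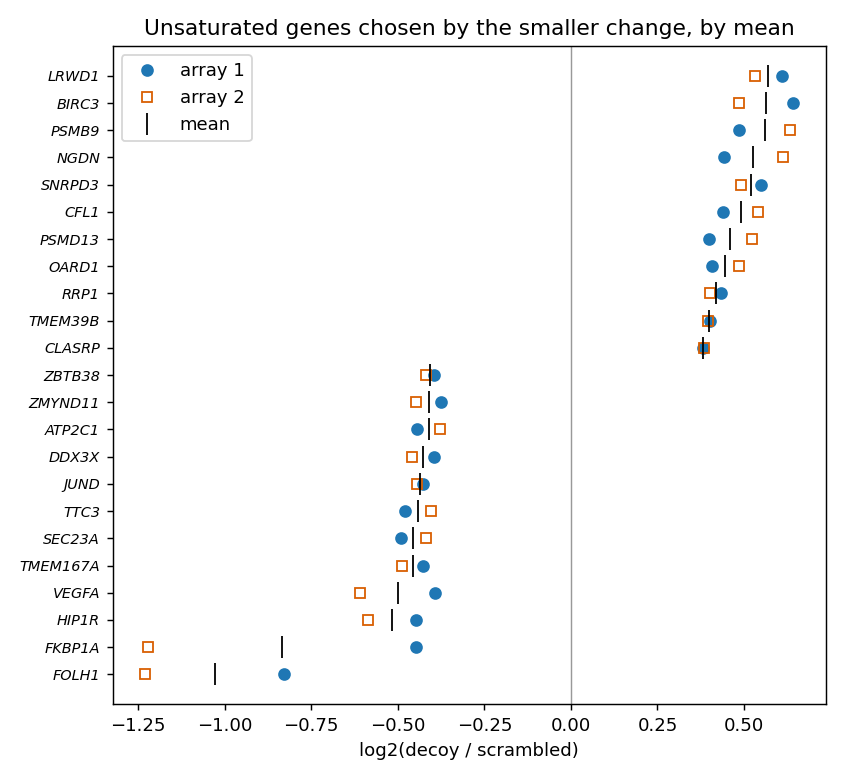
log2(decoy/scrambled) of higher and lower genes without a saturated spot, chosen by the smaller of their ratios and ordered by mean. Circles are array 1, open squares array 2 and bars their mean, in log2 units. FOLH1 lies lowest, at -0.83 and -1.23, and LRWD1 is highest by mean, at 0.61 and 0.53.

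In the fit as planned, with saturated probes, 9 of the 12 lower genes were shared with the list above, and OAT, VCL and UPF1 took the other places at -0.54, -0.55 and -0.57. In the fit without saturated probes OAT, VCL and UPF1 stood at -0.35, -0.37 and -0.41. All 12 higher genes were saturated in red on array 1. They were EEF1A1, FTH1P12, RNH1, STMN1, CCT4, RPS25, SOD1, TNFAIP2, DBI, MCM7, COX5B and UBOX5. Except for COX5B they were saturated in green as well, so their array 1 ratios, from 0.75 for UBOX5 to 0.78 for EEF1A1, are bounded in neither direction. Where red alone is saturated, the scrambled signal is cut off, so decoy/scrambled reads too high before normalization. The 1400 probes with red saturated on array 1 had a median of 0.55 on array 1 and 0.23 on array 2. Over all probes of the gene, RNH1 stood at 0.01 and UBOX5 at 0.03. Without saturated probes EEF1A1 stood at 0.13 and RNH1 at 0.05 as means. On array 2 the translation factor gene EEF1A1 stood at 0.88, the microtubule regulator gene STMN1 at 2.33, the replicative helicase gene MCM7 at 1.03 and the superoxide dismutase gene SOD1 at 0.83. FTH1P12 is a ferritin pseudogene whose probe can also take up transcripts of its parent gene. The lowest adjusted p among the higher and the lower genes was 0.662 in limma.

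Genes of the NF-kB inflammatory list, which holds cytokines and their feedback regulators, stood higher with decoy mainly on array 1, and few of them were saturated (3 of 24). Of 24 measured members, 19 were higher with decoy on both arrays and 1 was lower on both. Their median was 0.32 on array 1 and 0.02 on array 2, and camera gave an adjusted p of 2.39e-07 at the preset correlation. With an estimated correlation the camera adjusted p was 0.598. That test has a single residual degree of freedom with 2 arrays, and lists not called at the preset correlation, such as G2/M genes, had the same 0.598. A call lost in it therefore says little about a list, here and below. BIRC3 stood at 0.58 and 0.44 on the respective arrays, and CSF2, which encodes the growth factor GM-CSF, stood at 0.69 and 0.33. TNFAIP2 (0.77 and 1.43) and IER3 (0.71 and 0.67) were saturated in red on array 1, and TNFAIP2 in green as well. With red alone saturated, the array 1 ratio of IER3 reads too high before normalization. In the fit without saturated probes the list's median was 0.29 and 0.02 over 21 members (camera adjusted p = 5.61e-06, and adjusted p = 0.698 with an estimated correlation), with the adhesion molecule gene ICAM1 at 0.65 and 0.24 and the cytokine gene IL6 at 0.58 and 0.20. In the planned fit no member passed over all genes, and 1, IER3 with its saturated red signal, passed when adjusted over the list alone.

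The G1/S and replication list was also displaced upward, with 16 of 30 measured members higher on both arrays and 4 lower on both. Its median was 0.04 on array 1 and 0.08 on array 2 (camera adjusted p = 0.00238, and adjusted p = 0.598 with an estimated correlation). MCM7 (0.76 and 1.03), the thymidylate synthase gene TYMS (0.38 and 0.26), the thymidine kinase gene TK1 (0.73 and 0.21) and the sliding clamp gene PCNA (0.23 and 0.19) led the list, all saturated in red on array 1. MCM7 and TK1 were saturated in green as well. Without saturated probes its median over 25 members was 0.06 and 0.12 (adjusted p = 0.00469, and 0.698 with an estimated correlation), and with the software's background flags the call was lost (adjusted p = 0.123). The breast cancer metastasis list had 10 of 18 members higher on both arrays and medians of 0.09 and 0.05 (adjusted p = 0.034, and 0.598 with an estimated correlation). PLAAT4 stood at 0.59 and 0.31 with red saturated on array 1, the proteoglycan gene SRGN at 0.35 and 0.15, ADIRF at 0.13 and 0.74 and the protease gene ADAMTS1 at 0.17 and 0.12. Without saturated probes the medians were 0.06 and 0.04 over 17 members and the call ended, at an adjusted p of 0.065. It also ended with no filter on dim probes (adjusted p = 0.105), with processed signals (0.128), with the value table (0.357), with the median over all probes (0.051), with the long green values kept (0.267) and with the software's background flags (0.156). No member of either list passed, over all genes or adjusted over the list alone.

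Ribosomal protein genes and the commonly used reference genes carried the largest medians, and most of their members were saturated on array 1. For ribosomal proteins 45 of 49 members were higher on both arrays, with medians of 0.76 and 0.22 (camera adjusted p = 1.21e-19, and 0.598 with an estimated correlation), but 46 were saturated. In the fit without saturated probes a gene can be represented by a dimmer, unsaturated probe. The 7 ribosomal protein genes measured in it had medians of 0.06 and 0.20 (camera adjusted p = 0.065). RPS25 stood at 0.77 and 0.86, RPL11 at 0.73 and 3.92, RPL12 at 0.78 and 0.72 and RPL14 at 0.68 and 1.28, all saturated on array 1. The mean of RPL11, 2.33, depends on the background correction. It was 0.47 without correction and 0.81 with processed signals. Of the 18 reference genes 14 were saturated, and the list's medians of 0.61 and 0.17 (adjusted p = 6.02e-05, and 0.598 with an estimated correlation) became 0.04 and 0.10 over 9 genes without saturation (adjusted p = 0.11). ACTB stood at 0.57 and 0.43, GAPDH at 0.71 and 0.58 and B2M at 0.74 and 0.41, all saturated in red on array 1. GAPDH and B2M were saturated in green as well. HPRT1, which was not saturated, stood at -0.40 and -0.24 with a mean of -0.32. Its mean was -0.21 in the fit without saturated probes and -0.07 without background correction. With the software's processed signals it was 0.26, but these are not centred, with a median over all probes of 0.44 on array 2. TBP, the TATA-binding protein gene, stood at 0.03 and 0.12. In each of these lists 4 members passed when adjusted over the list alone and 0 over all genes.

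The other 14 lists did not pass camera in the planned fit. Oxidative phosphorylation genes passed with median centring (adjusted p = 1.97e-07), the value table and processed signals, G2/M and heat shock genes with median centring and the value table, DNA sensing genes with no filter on dim probes and with the median over all probes, and hypoxia and glycolysis genes with processed signals. Blood, endothelial and fibroblast markers passed with processed signals too, with a median of 0.11. Processed signals are not centred (median over all probes 0.0049 on array 1 and 0.44 on array 2), so the sign of that median does not give the direction against other genes. Interferon-stimulated genes, a known response to transfected DNA, had 12 of 33 members higher and 11 lower on both arrays, with medians of 0.03 and -0.00 (adjusted p = 0.794). ISG15 stood at 0.58 and 0.80 with red saturated on array 1, and IFITM1 at -0.31 and -0.67. The list of DNA sensing genes had medians of 0.05 and 0.00 (adjusted p = 0.105), and 0.08 and 0.06 without saturated probes, where it passed (adjusted p = 0.024, and adjusted p = 0.698 with an estimated correlation). Its helicase gene DHX9 stood at 0.20 and 0.19 and the nuclease gene MRE11 at 0.13 and 0.11. Factors known to bind AT-rich DNA had 9 of 41 members higher and 13 lower on both arrays (adjusted p = 0.272), led by the forkhead gene FOXN3 at -0.36 and -0.43 and by ARID5B at -0.41 and -0.18. Without saturated probes their means were -0.25 for FOXN3 and -0.27 for ARID5B. Cholesterol synthesis genes had 7 of 22 members higher and 10 lower (adjusted p = 0.187), with the lanosterol synthase gene LSS at -0.49 and -0.45 and ACAT2 at -0.30 and -0.31. Without saturated probes LSS had a mean of -0.31 and ACAT2 of -0.15.

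G2/M genes had 9 of 28 members higher and 8 lower on both arrays, with medians of -0.08 and 0.14 (adjusted p = 0.173), and CCNB1 (0.51 and 0.96) and UBE2C (0.60 and 0.35) were saturated in red on array 1. Unfolded protein and amino acid stress genes had 10 of 22 higher and 6 lower (adjusted p = 0.173), with the saturated regulator gene ATF4 at 0.71 and 1.07 (a mean of 0.14 without saturated probes) and the transporter gene SLC3A2 at -0.37 and -0.92. Heat shock genes (7 of 14 higher, adjusted p = 0.173) were led by DNAJA1 at 0.53 and 1.03 and HSPA4 at 0.35 and 0.84, both saturated. HSPA4 had a mean of 0.22 without saturated probes. Hypoxia and glycolysis genes (8 of 24 higher, adjusted p = 0.371) were led by VEGFA at -0.46 and -0.76 and the saturated ENO1 at 0.74 and 0.44. Oxidative phosphorylation genes had 12 of 33 higher and 9 lower (adjusted p = 0.173), with the saturated COX5B at 0.76 and 1.16 and COX8A at 0.70 and 1.08. Mesenchymal and matrix genes had 8 of 25 higher and 7 lower (adjusted p = 0.551), with the saturated CD44 at 0.39 and 0.39 and the cadherin gene CDH11 at -0.33 and -0.78. p53 targets had 6 of 21 higher and 6 lower (adjusted p = 0.311), and their median of -0.00 and mean of 0.06 differ in sign. BBC3, saturated in red on array 1, stood at 0.76 and 0.25 (a mean of -0.01 without saturated probes), and PMAIP1 at 0.20 and 0.19. Histone genes had 4 of 13 higher (adjusted p = 0.242), with H3C8 at 0.26 and 0.07 and H2BC8 at 0.04 and 0.03, the latter -0.04 as a mean under median centring.

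Neither list of cell type markers passed in the planned fit. Blood, endothelial and fibroblast markers had 2 of 20 higher and 7 lower on both arrays with medians of -0.02 and -0.00 (adjusted p = 0.173), led by PDGFRB at -0.14 and -0.27 and VWF at -0.08 and -0.09. With processed signals, whose ratios are not centred, their median was 0.11 (camera adjusted p = 0.00721). Epithelial and luminal markers had 2 of 19 higher and 7 lower (adjusted p = 0.579), with the desmosomal gene DSP at -0.31 and -0.29 and the saturated keratin gene KRT18 at 0.71 and 0.20. DSP had a mean of -0.16 in the fit without saturated probes. In these 14 lists, 0 members passed over all genes and 0 when adjusted over the list alone.

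**Figure D3:**
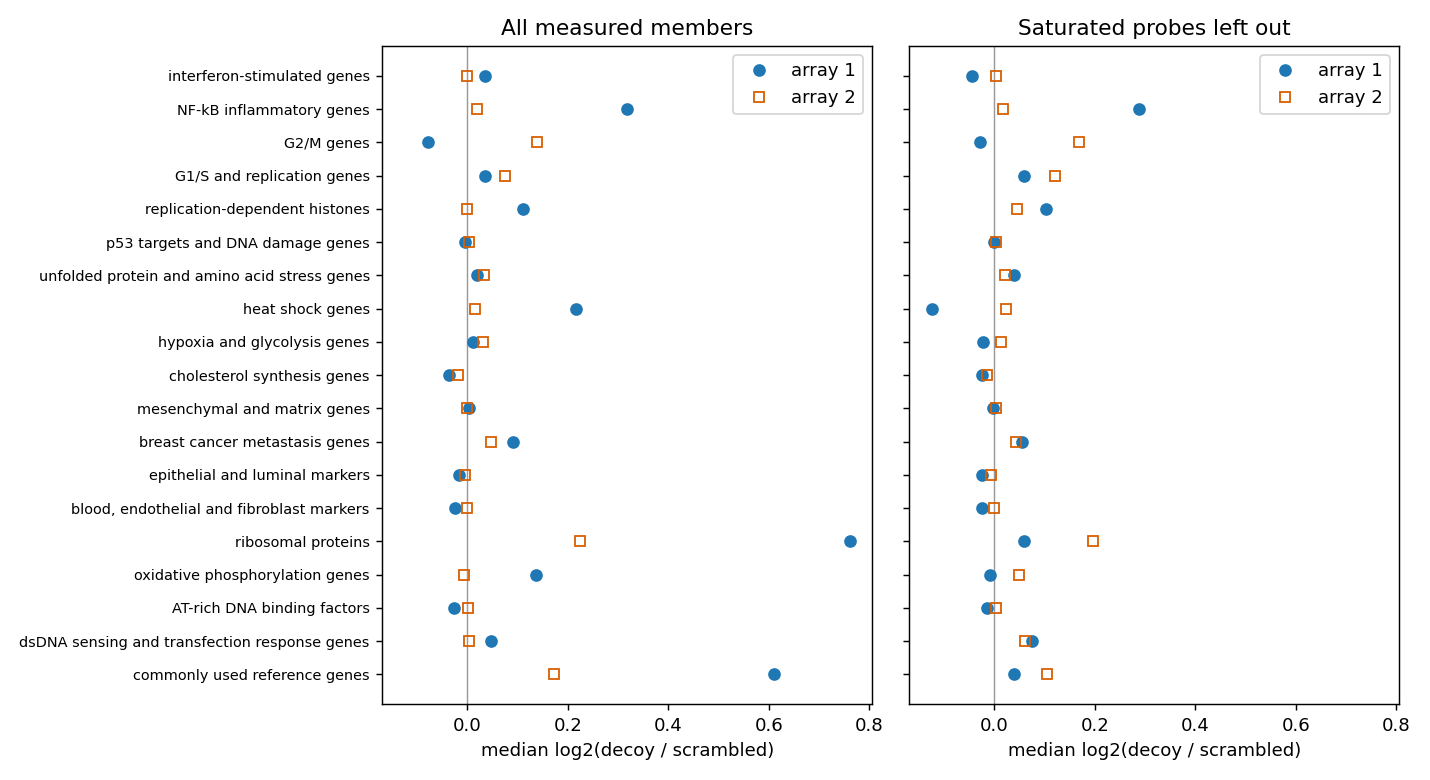
Median log2(decoy/scrambled) of the 19 gene lists on array 1 (circles) and array 2 (open squares), for all measured members (left) and without saturated probes (right). Ribosomal proteins lie at 0.76 and 0.22 with all members and at 0.06 and 0.20 without saturated probes, and the NF-kB list at 0.32 and 0.02 and at 0.29 and 0.02.

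The agreement of the arrays asks whether both decoys gave the same ratios. Across 26517 probes, which are not independent replicates, Pearson's r was 0.30 and Spearman's rho 0.20, and 56.4% of probes had the same sign. With median centring rho was -0.17 and 40.3% had the same sign. Over the 4466 probes left without non-uniform spots r was -0.013. The ratios of those probes spread little, with SDs of 0.084 on array 1 and 0.075 on array 2, against 0.19 and 0.21 over all tested probes. That r therefore does not show that the agreement comes from non-uniform spots. Without saturated probes r was 0.14. It rose with brightness, from 0.06 among unsaturated probes with a mean log2 intensity up to 10 to 0.53 among those above 14. For names as listed, with the features of long green values left out, r was 0.0041.

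**Figure D4:**
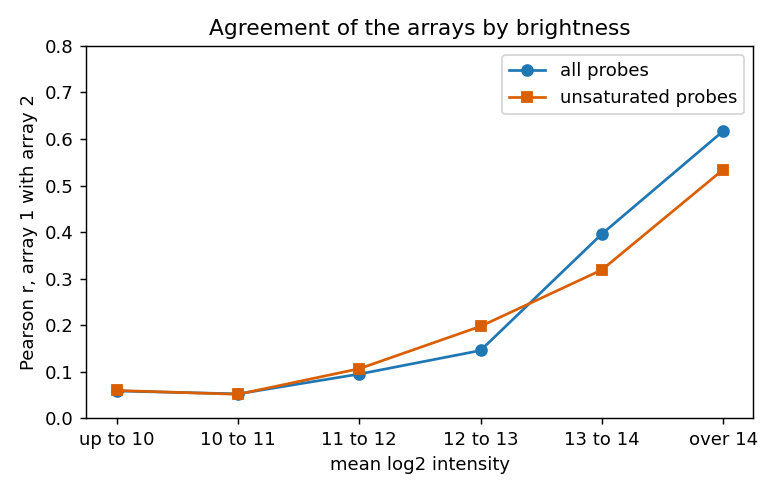
Pearson's r between the arrays' log2 ratios (y axis) by mean log2 intensity of the probe (x axis), for all tested probes (circles) and for unsaturated probes (squares). Both rise with brightness, to 0.62 and 0.53 above an intensity of 14.

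The scanner software's own error model, which covers the spots of a single hybridisation and compares those RNA samples only, called 757 probes higher and 8 lower with decoy on array 1. It called 51 higher and 167 lower on array 2. On both arrays 39 were called higher, against 1.14 for independent lists, and 0 lower, against 0.0395. All 39 had a saturated spot, as did 752 of the 757 called higher on array 1.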

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

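The tests on the deposited ratios were chosen after the result was seen. The features left out of the report carry a strong signal of their own. Over the 3637 features whose green values have more than 6 significant digits, the deposited log ratios correlated between the arrays at r = 0.72, and 88.4% had the same sign. Over the other 39739 non-control features r was -0.0029, which the layout fixes near 0, since the displacements differ and a listed position holds different probes on each array. With names in register the value table gave r = 0.13. The 3637 features were singled out because the comparisons do not use them and their r at listed positions lies above that level. The median deposited log2(decoy/scrambled) of these features was 0.76 on array 1 and 0.81 on array 2, and the software called 0 of them on either array.

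That these green values came from the scanner software as the others did is argued against by the p-values, of which at least 95.93% per array do not match their log ratio and its error, compared with 0% in the other features. That they show a response of the listed genes to the decoys is argued against by the moved layout. Over 2017 of these probes that were measured at their true spot, the deposited ratio and the measured one had a Spearman correlation of -0.1067 on array 1 (95% interval -0.150 to -0.0634). On array 2 it was -0.2231 (95% interval -0.264 to -0.181), so the relation was negative on both arrays. How the values arose stays open, since no source used here records it, and neither does this exclude a response too small for these arrays.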

How the results depend on the processing

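The layout, the treatment of the 3637 features, saturation, the software's background flags, spot flags and brightness were chosen as alternatives after the data were seen, and the others before. The count of probes past the threshold was 0 in every limma fit except with the software's processed signals, which gave 275, of which 44 had the same direction and an unadjusted p under 0.05 in the planned fit. The correlation of the arrays (0.30) was 0.23 without background correction, 0.12 with processed signals, 0.16 with median centring (Spearman -0.17) and 0.13 with the value table. It was 0.073 with the long-digit features kept in the moved layout, 0.0041 and 0.27 with names as listed without and with them, and 0.29 from the value table with names as listed. It was 0.36 with the software's background flags, 0.14 without saturated probes, -0.013 without non-uniform spots (4466 probes) and 0.38 above a log2 intensity of 12. In place of 5 lists, 8 were called with median centring, 7 with processed signals, 7 with the value table, 3 with the software's flags, 3 without saturated probes, 1 without non-uniform spots, 2 and 0 with names as listed with and without the long-digit features, and 0 with an estimated correlation, with or without saturated probes, and 0 with fry. The counts of 0 with an estimated correlation and with fry were close to fixed in advance, since 2 arrays leave these tests a single residual degree of freedom. The software's calls on array 2 fell to 112 at p under 0.001 and to 56 after adjustment.

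List medians turned in direction with names as listed, where the spots read for a list belong to other probes. Such medians therefore do not test the shifts. Without the long-digit features NF-kB genes stood at -0.0067 and ribosomal proteins at -0.045, and the uncalled G2/M genes at -0.23. With them G2/M genes stood at -0.34, ribosomal proteins at -0.059 and reference genes at -0.0040. In the value table with names as listed these were -0.59, -0.70 and -0.72, and G1/S genes stood at -0.0022. Metastasis genes stood at -0.013 without non-uniform spots, and blood, endothelial and fibroblast markers at 0.11 with processed signals. Processed signals are not centred, with a median over all probes of 0.0049 on array 1 and 0.44 on array 2. A turn to a positive value in them does not show a change against other genes. Among genes, FKBP1A (0.0061), ATP2C1 (0.015) and VEGFA (0.017) turned with the median over probes, and H2BC8 (-0.036) with median centring. UBOX5 (-0.036) and BBC3 (-0.014) turned without saturated probes. HPRT1 (0.26) turned with processed signals, whose ratios are not centred. Of 372 list values under the alternatives 303 kept their side of the threshold or stayed within the spread of the arrays, 34 lost and 12 gained a call in the same direction, 12 moved and 11 with a call in either fit turned. Counting those that turned, 39 calls were lost and 15 gained, and 42 values with no call in either fit changed direction. Some of those 42 came from processed signals or the value table, whose ratios are not centred. Among the lost calls, 5 each came from fry and from the estimated correlation with and without saturated probes, where hardly any list could pass. Of the 11 list values that turned, 2 came from names as listed without the long-digit features and 3 with them. A further 4 came from the value table with names as listed. Some lost calls came from these settings too, which read the lists at other probes' spots. Of 560 gene values 371 stayed within the spread of the arrays, 182 moved and 7 turned. Each array alone gave 84 of the values that stayed. Their outcome was fixed in advance, since each of 2 ratios lies within their SD of the mean and the genes were chosen for a shared direction. The cause of the changes was not tested. The promoter comparison was not run.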

Other observations

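The tests on the long green values, on saturation among bright probes and the 3 tests of explanations for the NF-kB shift were chosen after the results, or closely related values, had been seen. Only the tests on probe pairs and base composition were set out before. Among the genes that carry long green values, ribosomal protein genes (16 of 51 on the array, adjusted p = 0.00509, Fisher's exact test, two-sided, over 19 lists) and oxidative phosphorylation genes (13 of 38, adjusted p = 0.00509) were more frequent than the 12.7% of all genes. A gene counted if any of its probes carried such values, so genes with more probes count more easily. The test does not adjust for the number of probes per gene. In these features 26 of 27 ribosomal protein probes were listed as lower with decoy on both arrays, and 8 of 9 G2/M probes likewise (9 of 34 G2/M genes, adjusted p = 0.207). Probes of AT-rich DNA binding factors went the other way, with 15 of 18 higher on both arrays, and over all 3637 features 2393 were higher and 1244 lower on array 1. As printed, these are deposited values whose origin is open.

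The agreement of the arrays among bright probes is a pattern that a response shared by the decoys could give. Saturation as the whole cause is argued against by r = 0.2646 over 4569 unsaturated probes above a log2 intensity of 12 (95% interval 0.237 to 0.291). Base composition is argued against by r = 0.2379 once the GC share and intensity were regressed out. A dye bias of single probes stays open, because different probes of a gene correlated between the arrays at 0.1109 (95% interval 0.0487 to 0.167, 444 pairs, bootstrap over genes), below the 0.319 of the same probes. Within array 1 such pairs correlated at 0.376 and within array 2 at -0.0064, so array 2 carried little that was shared between probes of a gene. Dyes were not swapped, so a dye effect common to a gene's probes cannot be told apart from an effect of the decoys.

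The NF-kB list stood higher with decoy, and whether this is a response to the decoys was not tested apart from the points below. Saturation is argued against by the list's median on array 1 without saturated probes, at percentile 100 of random lists matched on intensity. A difference in the interferon response stays open in the planned fit, since the median of the interferon list lay at percentile 97.02 on array 1 and 23.68 on array 2. Without saturated probes it lay at 11.55 and 24.12, so the unsaturated members as a set showed no upward shift on either array. Single members of the list go both ways. Whether the shift lies on array 1 alone stays open, since the list's median on array 2, 0.02, lay at percentile 96.32 (93.57 without saturated probes). A dye effect stays open as well.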
